A study of Arabidopsis thaliana with 8 samples.

How the data were processed

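Total RNA of Arabidopsis thaliana rosettes was extracted with Trizol and 15 ug was used for biotin-labelled cRNA, per the labels' protocols. Plants grew at 22 °C with 14 h of light, and the line overexpressed MIL4. The run records name the chip type, and each array was hybridised with the same protocol on 1 of 4 days, called day 1 to day 4 here. H2O 2 and BTH 3 were hybridised on day 1, H2O 1, H2O 3 and BTH 4 on day 2, H2O 4 and BTH 2 on day 3, and BTH 1 on day 4. The run records also give a fluidics module. It was module 3 for H2O 1, H2O 2 and H2O 4, and module 1 for H2O 3 and BTH 1. It was module 4 for BTH 2 and BTH 3, and module 2 for BTH 4. Module 1 alone held both groups, so an effect of the module can hardly be told apart from that of BTH and was not tested.

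The deposited values are linear intensity signals, 1 per probe set and array, all above 0. From the values, each array's mean after leaving out the lowest and highest 2% was 500.04 or 500.05, so the authors had scaled the arrays to a common level before deposit. The software, background correction and summary method are not given in the sources used here. Because such scaling fixes the mean level of every array, a change shared by all transcripts would not show.

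The deposited table held 22810 probe sets, of which 64 control probe sets were left out of the comparison and 22746 were tested. The annotation table paired 13513 probe sets with 1 gene and 503 with several genes, and 8730 tested probe sets were unnamed here. Of the probe sets with 1 gene, 13436 were matched to current locus tags of the RefSeq annotation of assembly TAIR10.1 by gene identifier. No probe set was named MIL4, so the transgene was not analysed here. Genes with several probe sets were represented in lists by the single-gene probe set with the highest mean.

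Signals were transformed to log2(signal + 16), as planned for linear values, so that fold changes of weak probe sets are understated. BTH was compared with H2O with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p below 0.05 over all tested probe sets), with all 8 arrays and no covariates. Fold changes are BTH minus H2O on that scale. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of their kind, and again with an estimated correlation. Before the data were examined, 24 lists with 433 genes were fixed, of which 72 genes were measured by a single-gene probe set, and 12 lists had the minimum of 3 measured genes. A further 21 lists were defined by locus or symbol after the annotation was seen but before any comparison was computed, and 20 of them were tested. Of 24 family patterns searched in symbols and synonyms, 11 had at least 5 genes and were tested. The pattern for AP2/ERF factors matched clone names and was left out.

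Named genes followed a rule fixed before the data were examined. It named PR1, PR2 and PR5. It also named the 6 highest and 6 lowest fold changes among called single-gene probe sets above the median level with non-overlapping groups. From each fixed list came the 2 called members with the largest change, or up to 4 for a called list. Where no member was called, the brightest was taken. Families had at most 2 by the same rule, which was carried over to the added lists. Other members named beside them, such as AT1G11860, WRKY22, LTI30 and AT3G62950, were chosen after their values were seen.

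Alternatives were the replicate number or hybridisation day as a block, quantile normalization, median centring, leaving out probe sets below the 40th percentile of the mean, a variance trend with robust moderation, array weights, pseudocounts of 1 and 64, a threshold of 0.01, a treat test against a 1.2-fold change, fry, which tests a list against no change where camera tests it against the other genes, and leaving out each array in turn. Chosen after seeing the data were hybridisation day as a random block, leaving out day 3, all alternatives of the added lists, and those of the families other than the replicate block, the arrays left out and the estimated correlation. In simulated data with the spread of these arrays, limma recovered 28.4% of 67 probe sets changed 1.5-fold, 41.8% of 67 changed 2-fold and 83.3% of 66 changed 4-fold among 22746, and 9.73% of its calls were unchanged probe sets, above the nominal 5%. Camera called 10 of 10 simulated lists shifted by 0.5 log2 and 1 of 30 unshifted ones, both with 17 and with 4 genes per list, the smaller size added after seeing the data. The simulated genes were independent, so these rates do not cover lists of correlated genes. The limma simulation left 22546 of the 22746 probe sets unchanged, a larger share than the 2852 calls in these data leave. The adjusted cut-off depends on that share, so the limma recovery and the 9.73% need not hold for these data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.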

Results

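The arrays held whole rosettes of 1 Arabidopsis thaliana line that overexpresses MIL4 (MILDEW-INDUCED LESIONS 4), collected from plants 4 weeks old. Plants had been sprayed 2 days earlier with water (4 arrays, called H2O 1 to H2O 4) or with 300 uM BTH (4 arrays, BTH 1 to BTH 4). BTH, benzothiadiazole, is a synthetic compound that acts like salicylic acid and switches on systemic acquired resistance. Each array carried biotin-labelled cRNA and gave 1 signal for each of 22746 probe sets besides the controls. Median signals lay between 161.5 and 173 scaled units per array, and the number of arrays limits the precision. The labels call the arrays of a group biological replicates but do not say how the plants were grown apart, so the p-values measure the spread between these 8 samples. The comparison asks which transcripts differed after BTH in this line. No other genotype was analysed here, so nothing below measures the effect of MIL4 overexpression itself.

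Among the genes named by the fixed rule, the strongest rises with BTH were those of AT2G44240, AT3G49340 and CHI, and the strongest fall was that of COR15A. Signal of AT2G44240 rose from 110.1 ± 35 to 4687 ± 353 (mean ± SD, n = 4 in each group), a log2 fold change of 5.26 ± 0.21 (SE, adjusted p = 2.67e-05). CHI, the chitinase gene AT2G43570, rose from 903 ± 251 to 10883 ± 1735 (log2 fold change 3.59, adjusted p = 7.08e-05). AMY1, which encodes an alpha-amylase, rose from 152 ± 27.4 to 1804 ± 234, and CCOAMT, a caffeoyl-CoA O-methyltransferase gene, from 262 ± 91.8 to 2143 ± 386. The calmodulin-like gene CML41 rose from 202 ± 51.3 to 1646 ± 258 and AT3G49340 from 74.7 ± 13.6 to 1167 ± 269. COR15A, a cold-regulated gene for a chloroplast stromal protein, fell from 1973 ± 347 to 265 ± 54.7 (log2 fold change -2.83 ± 0.17, adjusted p = 9.38e-05). Among the other strongest decreases were AT1G30250 (log2 fold change -1.93, adjusted p = 0.000417), AT3G60290 (-1.87, adjusted p = 0.0014) and AT1G62510 (-1.81, adjusted p = 0.000461). AT4G17470 (-2.02, adjusted p = 0.0191) and AT3G28220 (-1.98, adjusted p = 0.00879) fell as well, with adjusted p of 0.114 and 0.0894 once hybridisation day was a block.

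**Figure D1:**
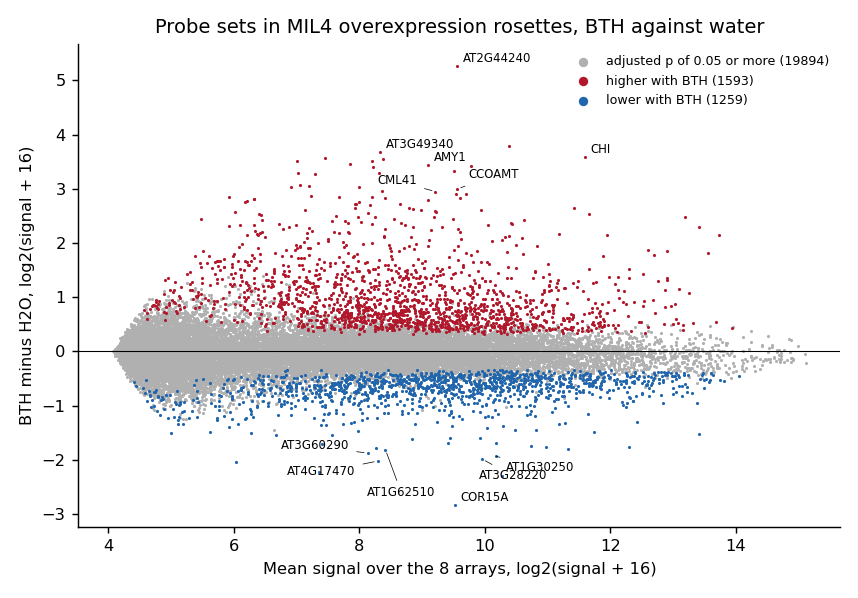
Change with BTH (BTH minus H2O, log2 of signal plus 16) against the mean level over the 8 arrays (log2 of signal plus 16), with 1 point per probe set. Red points are the 1593 probe sets called higher, blue points the 1259 called lower and grey points the rest, and the labelled genes are the 6 highest and 6 lowest named by the fixed rule.

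In all, 2852 of the 22746 probe sets (12.5%) changed at an adjusted p below 0.05 in limma, 1593 of them higher and 1259 lower with BTH. Which direction held more depended on the scaling, with 1394 higher and 1587 lower after median centring and 1496 higher and 1402 lower after quantile normalization. The larger changes were mostly increases: of 740 probe sets that changed at least 2-fold, 598 rose and 142 fell, and 123 rose but 5 fell at least 4-fold. The 4 BTH arrays lay wholly above or below the 4 H2O arrays for 4541 probe sets (19.96%), where chance gives 2.86%. Of the changed probe sets, 1460 were paired with 1 gene, 786 higher and 674 lower. Arrays were hybridised on 4 days, and 3 of these days held both groups. With hybridisation day as a block, a fit in which BTH 1 carries no information because it was alone on its day, 1513 probe sets passed (943 higher, 570 lower). Without the arrays of day 3, H2O 4 and BTH 2, which stood apart on the second principal component, 1463 passed (920 higher, 543 lower).

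**Figure D2:**
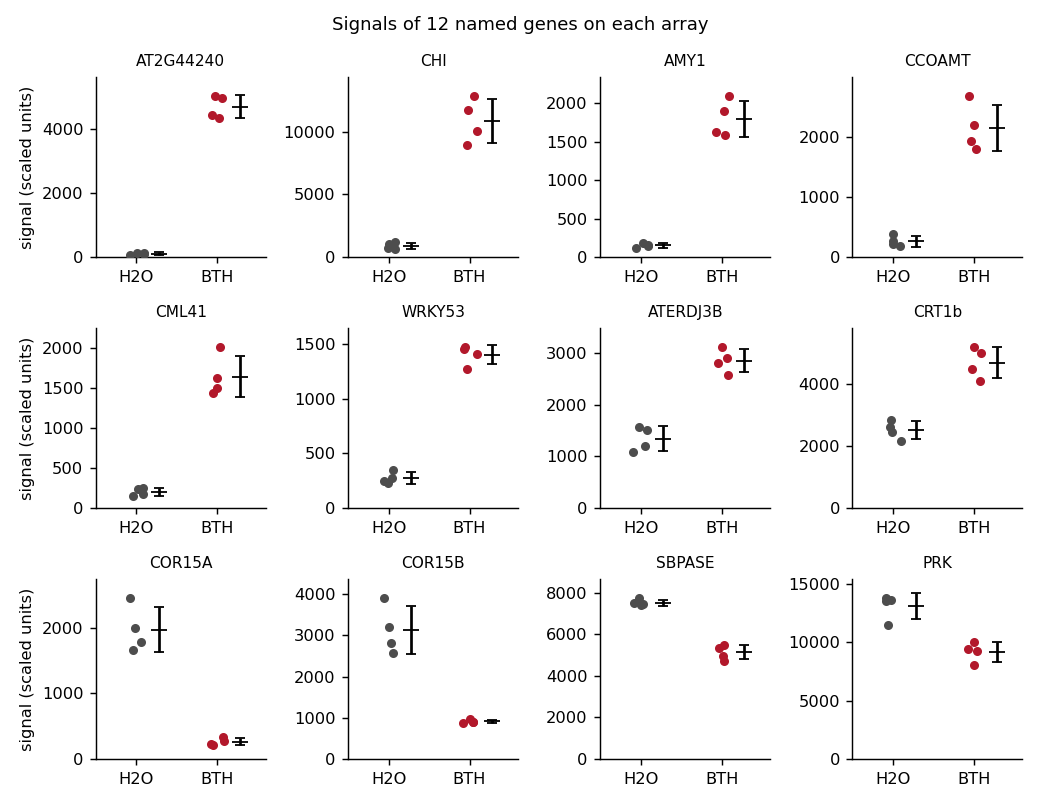
Scaled signal on each array for 12 of the named genes, with H2O arrays in grey and BTH arrays in red; the bar beside each group is the mean ± SD over 4 arrays, and every axis starts at 0. For all 12 genes the 4 BTH arrays lie wholly above or wholly below the 4 H2O arrays. The naming rule required this of AT2G44240, CHI, AMY1, CCOAMT, CML41 and COR15A, and the other genes shown were picked from the called ones, so it is no separate evidence.

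The measured genes of the list of protein folding and secretion in the endoplasmic reticulum rose together, 7 of the 33 listed. The larger added list of ER translocation, glycosylation and vesicle coats, described under other observations, had 2 of 35 members called (camera, adjusted p = 0.0504). All 7 measured members of the folding and secretion list rose, 7 also when adjusted over the list alone, with a median log2 fold change of 0.73. Camera gave an adjusted p of 5.79e-06, and of 0.0497 with an estimated correlation. The DnaJ co-chaperone gene ATERDJ3B rose from 1343 ± 237 to 2847 ± 221, and the calreticulin gene CRT1b from 2519 ± 283 to 4694 ± 503. BZIP60, a transcription factor of the unfolded protein response, rose 1.81-fold (adjusted p = 0.00892) and the calnexin gene AT5G07340 rose 1.66-fold (adjusted p = 0.00571, and 0.0503 without day 3). The list's median was 0.47, 0.65 and 0.82 on days 1, 2 and 3, and 0.67 with day as a block (adjusted p = 4.82e-05).

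Most measured genes in the list of the response to abscisic acid, cold and drought fell. Only 4 of the 18 listed genes were measured, so the result does not cover that response as a whole. Of 4 measured members 3 fell, and 4 did so when adjusted over the list alone, with a median log2 fold change of -1.25 (camera, adjusted p = 3.39e-05; adjusted p = 0.0497 with an estimated correlation). The fallen members were COR15A, COR15B (3129 ± 582 to 914 ± 38.2) and COR47 (5098 ± 124 to 3045 ± 454). LTI30 was not called over all probe sets (log2 fold change -0.31, adjusted p = 0.116). Medians on days 1 to 3 were -1.02, -1.44 and -1.25, and the median with day as a block was -1.26 (adjusted p = 0.000461).

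Some measured genes of salicylic acid signalling and of the WRKY transcription factor family rose, in small lists of which none was called with an estimated correlation. The estimate was 0.20 for the salicylic acid list. For the list of defence-linked WRKY factors and the 7 annotated WRKY genes it was -0.13 and -0.08, below the preset 0.01. A higher correlation among members is thus not what raised the adjusted p of the WRKY lists. WRKY53 rose from 274.5 ± 52.7 to 1401 ± 89.8 and WRKY6 from 103 ± 15.6 to 211 ± 21.4, while WRKY22 had a log2 fold change of -0.19 (adjusted p = 0.576). The list of defence-linked WRKY factors thus had 2 of 3 members higher, 2 also adjusted over the list alone (camera, adjusted p = 0.0227; adjusted p = 0.126 with an estimated correlation), and its adjusted p was 0.0582 without BTH 3. Among 7 annotated WRKY genes 3 rose, WRKY47 among them (166 ± 28.2 to 506 ± 57.5; camera, adjusted p = 0.00659; adjusted p = 0.135 with an estimated correlation). Of 4 measured salicylic acid genes 2 rose, 2 also adjusted over the list alone (camera, adjusted p = 0.0401; adjusted p = 0.281 with an estimated correlation). These were AT5G52810, a gene of pipecolic acid synthesis (301 ± 26.7 to 754 ± 162), and SAG101, whose product acts with EDS1 (186 ± 52.7 to 418 ± 107). BSMT1 and UGT76B1, the members not called, had mean signals of 14.5 and 20.7 with H2O and 18.65 and 31.3 with BTH. Such weak signals, close to the added 16, say little about whether these genes responded. Without H2O 3 this list had an adjusted p of 0.0626. Day medians were 1.05, 0.83 and 0.72 for the WRKY list and 0.85, 0.97 and 0.75 for the salicylic acid list, with adjusted p of 0.0234 and 0.0363 when day was a block. The pathogenesis-related genes PR1, PR2 and PR5 were not analysed here.

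Some genes of photosynthesis and of plastid ribosomes fell, in lists of which none was called with an estimated correlation. In the list fixed before the data were examined, 2 of 5 measured members fell, 2 also adjusted over the list alone: the Calvin cycle genes SBPASE (7530 ± 149 to 5135 ± 342) and PRK (13118 ± 1097 to 9202 ± 862). The list's median was -0.24 (camera, adjusted p = 0.046; adjusted p = 0.38 with an estimated correlation), with -0.27, -0.29 and -0.32 on days 1 to 3 and an adjusted p of 0.0173 with day as a block. Its adjusted p was 0.145 without day 3, 0.13 with quantile normalization, 0.0729 without dim probe sets, and 0.0566, 0.0574, 0.143, 0.106 and 0.0826 without H2O 1, H2O 3, H2O 4, BTH 3 and BTH 4. PRK alone had adjusted p of up to 0.0991 under the alternatives. Among lists added once the probe annotation was known, 6 of 9 nuclear genes for plastid ribosomal proteins fell (camera, adjusted p = 0.000164; adjusted p = 0.242 with an estimated correlation). In further genes of photosynthesis and photorespiration 3 of 11 fell (adjusted p = 0.000198; adjusted p = 0.242 with an estimated correlation), and these were the glycine cleavage genes AT1G32470 (7465 ± 476 to 4871 ± 257) and AT1G11860 and the glycerate kinase gene AT1G80380. Of 13 genes of tetrapyrrole and chlorophyll synthesis 1 fell, LIL3:1 (adjusted p = 0.0273 for the list; adjusted p = 0.281 with an estimated correlation). That list had 0.114 without day 3, 0.0523 with quantile normalization and 0.0602 without BTH 2, and LIL3:1 alone had up to 0.16 under the alternatives. Day medians were -0.36, -0.46 and -0.57 for the plastid ribosomal genes and -0.30, -0.38 and -0.46 for the further photosynthesis genes. None of 69 probe sets of the plastid genome passed in limma (median -0.22, camera adjusted p = 0.0802), where the list had an adjusted p of 0.000261 without H2O 1, 0.0408 without H2O 2, 0.0115 without BTH 2 and 0.049 with a variance trend. Without H2O 4 its median was -0.0054 and the test's direction upward (adjusted p = 0.949), and the day medians were -0.10, 0.20 and -0.47. Its adjusted p was 0.16 with day as a block, 0.4 without day 3 and 0.797 with an estimated correlation.

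**Figure D3:**
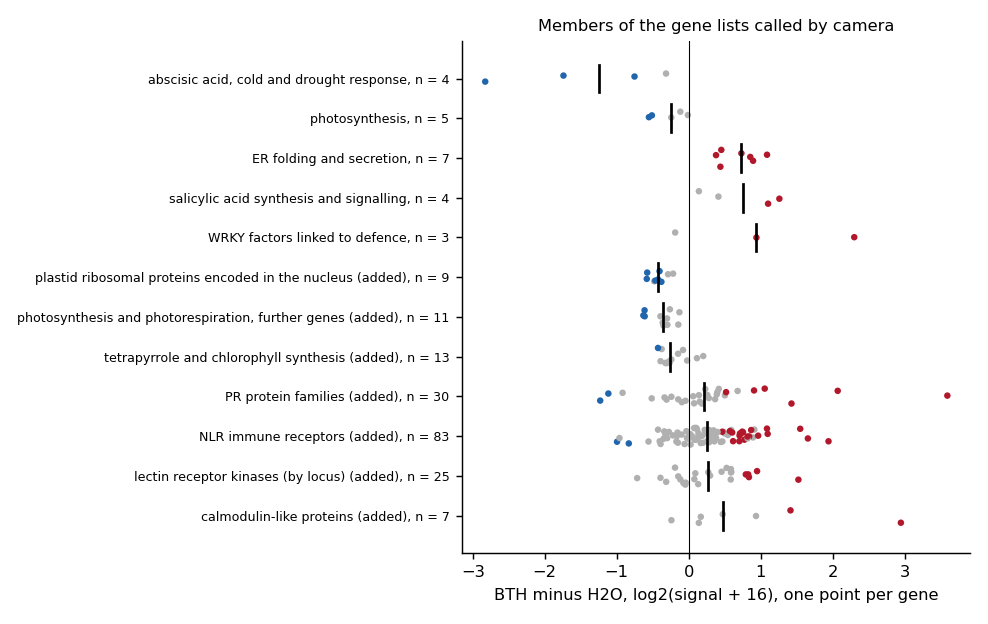
Log2 fold change (BTH minus H2O, signal plus 16) of each measured member of the 12 gene lists that camera called with its preset correlation; red and blue points are members called higher and lower, grey points are not called, and the black bar is the list's median. The lists marked added were defined after the probe annotation was seen, and of the 12 lists, ER folding and the cold and drought list had an adjusted p below 0.05 with an estimated correlation.

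Some genes of immune receptors and pathogenesis-related families rose, in lists added once the annotation was known, none of them called with an estimated correlation. That estimate was 0.03 for the NLR list and 0.05 for lectin receptor kinases. It was -0.01 for pathogenesis-related families and -0.05 for calmodulin-like genes, below the preset 0.01. A higher correlation among members is thus not what raised the adjusted p of the last 2 lists. Of 83 genes listed as NLR receptors 20 rose and 2 fell (camera, adjusted p = 0.000164, and adjusted p = 0.209 with an estimated correlation). They were led by AT1G57630 (220 ± 80.1 to 858.5 ± 104) and AT5G58120 (105 ± 18.5 to 369 ± 90.0). The annotation used gives no protein domains, so some members, AT1G57630 among them, may not be NLR receptors in the strict sense. Of 25 lectin receptor kinase genes 5 rose and none fell (adjusted p = 0.0273; adjusted p = 0.242 with an estimated correlation, 0.0706 without H2O 2, and 0.0826 without dim probe sets), AT1G61420 by a log2 fold change of 1.52. Among 30 genes of pathogenesis-related families 6 rose and 2 fell (adjusted p = 0.0395; adjusted p = 0.209 with an estimated correlation). Chitinase CHI and the osmotin-like gene OSM34 (79.4 ± 39.2 to 360 ± 68.9) were the strongest of them. That list had an adjusted p of 0.0635 with day as a block, 0.0509 without day 3, and 0.0633 and 0.0611 without H2O 4 and BTH 4. Of 7 calmodulin-like genes CML41 and CML37 rose (adjusted p = 0.0273; adjusted p = 0.209 with an estimated correlation, and 0.171 without dim probe sets). With day as a block CML37 had an adjusted p of 0.0507. Day medians were 0.31, 0.21 and 0.30 for the NLR list and 0.43, 0.47 and -0.01 for lectin kinases. They were 0.15, 0.32 and 0.18 for pathogenesis-related families and 0.83, 0.53 and 0.51 for calmodulin-like genes.

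Other lists were not called as a whole, though single members changed. Of 17 measured glutaredoxin and thioredoxin genes 2 rose and 1 fell, 3 also adjusted over the list alone (camera, adjusted p = 0.438): AT5G11930 rose 3.85-fold, GRX480 rose 3.17-fold and AT3G62950 had a log2 fold change of -0.79. In the jasmonate list JMT, a jasmonate methyltransferase gene, fell (log2 fold change -1.25, adjusted p = 0.0124) as 1 of 4, 1 also adjusted over the list alone. That list had an adjusted p of 0.134, of 0.0173 with day as a block, 0.507 without day 3 and 0.38 with an estimated correlation, and JMT had 0.0791 without day 3. Of 4 auxin genes WES1 rose and IAA29 fell, 2 also adjusted over the list alone (list adjusted p = 0.595; IAA29 had 0.0599 without day 3), and of 3 wall-loosening genes EXPA8 fell, 1 also adjusted over the list alone (list adjusted p = 0.438; EXPA8 had 0.0738 without H2O 3). No heat shock gene passed in limma among 3 (list adjusted p = 0.438), nor did 3 root markers (adjusted p = 0.822) or 3 reference genes (adjusted p = 0.595), with 0 adjusted over the list alone in each. For the root markers the median was 0.21 but the mean -0.05 and the test's direction downward.

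Lists with fewer than 3 measured genes were not tested as sets. In them EFR, the receptor of bacterial elongation factor Tu (69.3 ± 22.4 to 144 ± 33.7, adjusted p = 0.0319), and the receptor-like kinase gene BIK1 (590 ± 69.8 to 953 ± 126, adjusted p = 0.0136) rose. UGT74B1 of glucosinolate synthesis (1029 ± 122 to 1799 ± 251, adjusted p = 0.00678) and the zinc finger gene STZ (496 ± 51.9 to 778 ± 129, adjusted p = 0.0223) rose as well. Under the alternatives the adjusted p reached 0.0921 for EFR, 0.0792 for BIK1 and 0.106 for STZ. The log2 fold change was -0.20 for GSTU22, 0.03 for EIN3, 0.17 for UGT78D2, 0.18 for SAG29, -0.17 for GI and -0.02 for the guard cell gene FMA, with adjusted p between 0.272 and 0.946. SAG29, at 6.3 ± 4.2 with H2O and 9.6 ± 7.1 with BTH, lay below the added 16 and says little about a change. GSTU22 was weak as well (41.5 ± 24.4 with H2O, 31.3 ± 4.2 with BTH). EIN3 was at -0.02 after median centring.

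No difference between the groups in the 3' to 5' signal of control transcripts was called by an exact permutation test. Single control probe sets that did differ are described below, where fewer intact 5' ends in a group stay open. For 6 pairs of control probe sets at the 3' and 5' ends of actin, GAPDH and ubiquitin transcripts, the 3' minus 5' difference in log2 signal had exact two-sided p between 0.2 and 0.886, where 4 against 4 arrays allow 0.0286 at the lowest. Correlations of log2 signals across probe sets were 0.975 to 0.978 within H2O, 0.978 to 0.982 within BTH and 0.956 to 0.971 between groups. These are correlations across genes, which are not independent replicates.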

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

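In this part, the tests of RNA integrity and of hybridisation day were chosen only after the result was seen. Calling BTH against H2O gave 2852 probe sets. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many, the real one, and the highest of the other splits gave 2. A share of 1 in 35 is the smallest this test can give, so it argues against chance only to that degree. The other splits mix both groups, which widens their spread, so the gap in counts adds no further evidence.

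Among 170 groups of 4 values checked for the named genes, 8 held an array far from the other 3, where chance gives about 1 in 20 (8.5). These were H2O 4 for WRKY6 (126.1, others 94.0 to 95.6) and AT5G11930 (29.5, others 60.1 to 64.4), and H2O 2 for PRK (11478, others 13563 to 13784), PUB24 (250, others 307 to 319) and EXLA1 (1085, others 884.5 to 888). The others were H2O 1 for Prx37 (142, others 28.7 to 37.2), BTH 3 for WES1 (993.5, others 1034 to 1036) and BTH 4 for GAMMA-VPE (7653, others 9310 to 9455).

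Control probe sets outside the comparison were brighter with BTH on all 4 arrays for 7 probe sets of plant transcripts, each at the lowest exact permutation p of 0.0286 and an adjusted p of 0.203 over 64 controls. With 4 arrays in each group p can go no lower, so the failed correction is no evidence against a difference. Their log2 differences were 0.45, 0.48, 0.34 and 0.42 for GAPDH, 0.29 and 0.36 for ubiquitin and 0.16 for actin. The 25S ribosomal RNA control had a mean of 547 ± 190 with H2O and 258 ± 101 with BTH (± SD, n = 4 each), with the same exact p. For the GAPDH pattern, RNA with fewer intact 5' ends in a group stays open. The 3' difference was 0.80 times the 5' difference for GAPDH and exceeded 0.5 times that difference by 0.13 ± 0.08 (SE), which is within 2 SE. Both ubiquitin values are from 5' probe sets, whose 3' partners differed by 0.11 and 0.06, or 0.37 and 0.18 times as much. A higher transcript level of cytosolic GAPDH genes may account for it and stays open as well: GAPC2, by its own probe set, had a log2 fold change of 0.12 ± 0.11 (SE, adjusted p = 0.574), which neither passes nor lies below 0.1.

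All 25 measured genes of photosynthesis, photorespiration and plastid ribosomes in the 3 lists had lower means with BTH, and 11 of them passed. A trend of the scaled signals with brightness is argued against as the only source, though less firmly than the random lists imply. Of 10000 random lists matched on mean signal, 0.02% had a median as low as -0.38, and their 2.5th percentile was -0.25. Their own median was -0.11, so part of the fall may go with brightness. The random lists drew probe sets independently of each other. The estimated correlation was 0.40 in the fixed photosynthesis list, 0.54 for plastid ribosomes and 0.28 in the further genes. Medians of correlated genes spread more, so 0.02% overstates how rare such a median is. With quantile normalization the median of the fixed photosynthesis list was -0.15 (camera, adjusted p = 0.13), while the other 2 of the 3 lists stayed called. Hybridisation day is argued against as well, since the median was -0.31 or lower on each of the 3 days with both groups. The fluidics module, which nearly follows the groups, was not tested. A response to BTH is therefore a candidate explanation, as a hypothesis found and tested on the same arrays, and the estimated correlation, under which none of the 3 lists passed, leaves open how firmly the genes count as separate evidence.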

How the results depend on the processing

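Hybridisation day as a random block, leaving out day 3, all alternatives of the added lists and those of the families beyond the planned ones were chosen after seeing the data. Replicate numbers did not pair the arrays: deviations from the group means correlated at 0.20, -0.14, -0.01 and -0.14 for numbers 1 to 4. With the replicate block the changed probe sets numbered 1513 (981 higher, 532 lower) and 18 named genes lost the call, SAG101 (0.0736) and AT1G80380 (0.0553) under this block alone. Under it the fixed photosynthesis list had an adjusted p of 0.0867 and the plastid genome genes 0.00415. With hybridisation day as a block they also numbered 1513 (943 higher, 570 lower), with 4 families called and 20 named genes losing the call; both blocks leave 3 residual degrees of freedom where 6 are available without them. Same-day arrays tended to deviate together (mean correlation 0.25, other pairs -0.08). This was reached by an exact one-sided share of 0.0417 of 24 assignments of days, the lowest share possible. The test was chosen after seeing the data. Same-day pairs ran from 0.05 (H2O 1 with BTH 4) to 0.37 (H2O 4 with BTH 2). H2O 1 and BTH 1, of different days, were at 0.20. As a random block, day gave 3201 probe sets, including 2852 of the 2852; camera takes no such block, so lists were not run with it. Without day 3 there were 1463 (920 higher, 543 lower), and 23 named genes lost the call. A threshold of 0.01 left 1313. At least 2-fold changes numbered 482 with pseudocount 64, and a treat test against 1.2-fold called 1114. With an estimated correlation 2 fixed lists, 0 added lists and 0 families were called. Leaving out 1 array gave 1902 to 2449 changed, 1134 to 1390 higher, 757 (without H2O 3; 791 without BTH 2) to 1059 lower, 670 to 798 at least 2-fold, 3 (without H2O 3 or BTH 3) to 5 fixed lists and 6 to 9 added lists. The other causes were not tested. No called named gene reversed; 41 of 70 passed in each alternative run and 29 lost the call in some. The sign of a gene's fold change, or for a list the direction of the test, turned only where the result did not pass. Some list medians given here therefore kept their sign. With quantile normalization atpB was at 0.040 and cytosolic ribosomal proteins at 0.0031. Without day 3 atpB was at 0.00044, with median centring EIN3 was at -0.021, and with day as a block FMA was at 0.019. With that block the test of the root markers turned upward, with a median of 0.39 (0.21 without the block). Without dim probe sets the test turned for PUB ligases (median 0.063), glutathione transferases (-0.078) and UDP-glycosyltransferases (-0.11), and for PUB ligases also with a variance trend (-0.15) and pseudocount 1 (-0.17). Over the arrays left out, values ran from -0.36 to 0.053 for GSTU22, -0.11 to 0.030 for FMA, -0.13 to 0.092 for atpB, -0.12 to 0.43 for root markers, -0.40 to -0.0054 for plastid genome genes, -0.12 to 0.13 for tetraspanins and -0.12 to -0.044 for PUB ligases. Changed probe sets numbered 2602 with pseudocount 1 and 3513 with 64, where weak signals weigh less, 3867 with a variance trend and robust moderation (2021 higher, 1846 lower) and 3784 without dim probe sets (1935 higher, 1849 lower).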

Other observations

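No enzyme or wall gene family was called as a whole by camera, which compares a family with the other genes. Of 43 UDP-glycosyltransferase genes 6 rose and 5 fell (camera over the family, adjusted p = 0.508), with UGT73D1 from 24.3 ± 14.5 to 419 ± 64.6 and UGT87A2 from 538 ± 93.6 to 2239 ± 269 (mean ± SD, n = 4). Of 24 cytochrome P450 genes 3 rose and 1 fell (adjusted p = 0.508), all within the CYP71B subfamily, where 18 genes were measured (adjusted p = 0.603); CYP71B23 rose 2.95-fold and CYP71B24 rose 2.62-fold. In the P450 family and in the CYP71B list the median was below 0 and the mean above it. Of 19 expansin genes 4 fell and 1 rose (adjusted p = 0.33), with EXPA16 from 560 ± 103 to 161 ± 65.3 and EXLA1 from 936 ± 99.5 to 483 ± 60.02. Of 9 peroxidase genes 3 rose and 1 fell (adjusted p = 0.33), of 17 pectin and wall enzyme genes 3 rose and 1 fell (adjusted p = 0.508), and of 13 glutathione transferase genes 1 rose (adjusted p = 0.508). The remaining families, EF-hand proteins, histones, photosystem subunits and Aux/IAA proteins, had adjusted p of 0.13, 0.209, 0.189 and 0.441. With hybridisation day as a block, EF-hand proteins (0.0253), histones (0.0471) and photosystem subunits (0.0253) were called, where an estimated correlation without the block gave 0.314, 0.444 and 0.53. Of the families not called by camera, fry, which tests against no change, called expansins (adjusted p = 0.00255, downward), EF-hand proteins (0.000381, upward) and histones (0.0277, downward).

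Of 32 malectin-like receptor kinase genes 5 rose (camera, adjusted p = 0.118), AT1G51890 from 103 ± 28.4 to 667 ± 90.6. The list's median was 0.03, but 1.03 without dim probe sets (adjusted p = 0.000743), the only call among 20 alternatives with camera. An estimated correlation gave 0.242, and fry against no change gave an adjusted p of 0.00682. Genes of ER translocation, glycosylation and vesicle coats had 30 of 35 positive fold changes, 2 of them called (adjusted p = 0.0504; adjusted p = 0.242 with an estimated correlation), and 6 of 20 alternatives with camera called the list, the lowest adjusted p being 0.0339 without H2O 1 (fry against no change, 0.00882). Cell division genes had a median of -0.23 with no member called by limma among 19 (adjusted p = 0.0512), and 9 of 20 alternatives with camera called the list, with adjusted p from 0.0293 without H2O 4 to 0.281 with an estimated correlation (fry against no change, 0.0221). Adjusted p was 0.603 for 42 cytosolic ribosomal protein genes, 0.687 for 16 mitochondrial genome genes, 0.376 for 10 autophagy genes, 0.332 for 14 SWEET transporter genes and 0.406 for 10 XTH genes, which had 0.0452 without dim probe sets. It was 0.687 for 15 tetraspanin genes, whose median was above 0 and mean below it, 0.939 for 9 PUB ligase genes and 0.221 for 4 vacuolar processing enzyme genes.

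Genes higher with BTH lay next to each other more often than in shuffled gene orders. Along 13217 ordered genes, 76 neighbouring measured pairs were both higher, against a mean of 45.9 and a central 95% of 34 to 59 in 10000 shuffles, which argues against a chance order (permutation p = 1e-04, the smallest the shuffles can give). Genes lower with BTH formed 48 such pairs, against a shuffled mean of 33.5 (permutation p = 0.007). Probe sets marked as matching several transcripts are argued against as the source, because 75 pairs were counted without them and the ratio of observed to shuffled pairs was 1.62. Unmarked probe sets that detect similar copies are not covered by this and stay open. The 5 runs of 3 were AT1G65490 to AT1G65510, AT4G26060 to AT4G26130, AT4G38540 to AT4G38560, AT5G11910 to AT5G11930 and AT5G52740 to AT5G52760. Only measured genes were ordered, so neighbours can have other genes between them. The run AT5G11910 to AT5G11930 held cwINV6 beside the glutaredoxin gene AT5G11930, so it is not made of copies alone. Shared regulation of tandem gene copies may explain part of the excess of pairs, but no biological explanation was tested.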
